A study of Mus musculus with 10 samples.

How the data were processed

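RNA of primary cortical neurons from foetal Swiss albino mice (gestation day 15 to 16) was measured on 10 Affymetrix arrays, 1 per sample. Per the labels' protocols, the cultures were treated on day 5 in vitro with 1 µM lactacystin, an inhibitor of the proteasome, in a serum-free medium, and 7 µg of total RNA went into each labelling reaction. The control groups held 2 arrays at 24 h and 2 at 48 h, and the lactacystin groups 3 at each time. The labels do not say whether the controls received the solvent, nor whether replicates were separate cultures, so p-values measure the spread between these samples, which may be technical.

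The deposited values are intensities, 1 summary signal per probe set on a linear scale, and MAS5 is named per the submitters' processing notes, with its version not given in the sources used here. Array designs were mixed: replicate 1 of both control groups, replicate 1 of lactacystin at 24 h and replicate 3 of lactacystin at 48 h were on U74A, and the other 6 arrays on its revision U74Av2. The 2 designs are separate deposited tables. For U74Av2 there were values of 12488 probe sets and for U74A of 10043, each of which was also among those of U74Av2. In the values, each U74Av2 array had a trimmed mean of about 500 over all its probe sets. Any difference of culture batch or processing date between the designs cannot be told apart from the design. Median signals ran from 140.6 to 234.1, and detection calls were not used here. The number of arrays limits the precision.

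The 66 control probe sets were left out. Each array was scaled over the shared probe sets to a 2% trimmed mean of 500, a pseudocount of 32 was added, and log2 was taken. Fold changes are therefore on the log2(value + pseudocount) scale, which understates the change of low genes; 19.9% to 27.8% of the values of an array lay under the pseudocount. Of the 9977 shared probe sets, the 2993 with the lowest mean over all arrays (30%, a scaled signal under 51.3) were left out, and 6984 were tested. Probe sets were named through the platform annotation, with symbols updated by Entrez identifier through a RefSeq gene table of assembly GRCm38.p6 for 10839 of the 10855 probe sets annotated with 1 symbol. Of the shared probe sets, 8724 carried 1 symbol, 346 several and 907 none, and none was named from a probe set with several. The tested probe sets stood for 5542 named genes. For gene lists and named genes, the probe set with the highest mean signal stood for its gene. No genome coordinates are given, since the sources name no build.

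Tests used limma 3.58.1 in R 4.3.3. The 4 groups of agent and time were fitted together on all 10 arrays, with array design as a covariate, leaving 5 residual degrees of freedom (6 for the comparison over both times, which had time and design as covariates). Moderated tests (lmFit, eBayes with trend) were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the 6984 probe sets, with a threshold of 0.05. Every adjusted p of a gene in the text is from these limma fits, and errors are standard errors (SE) of the log2 change. The 29 lists (22 of pathways and complexes, 7 of cell type markers) and the design were fixed before the data were examined. Lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, with fry as an alternative, and adjusted over the 29 lists. A list's median is over its measured genes.

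Named genes followed a rule fixed at the same time. For each of the comparisons at 24 h and at 48 h, these were the 12 largest rises and the 12 largest falls past the threshold with the same sign in both array designs, and for other comparisons 5 and 5, or the 5 smallest p where none passed. Up to 4 members of each list with the largest change at 48 h were added. Other genes named here were chosen after their values were seen. Other probe sets of the named genes did not oppose a call in direction.

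The fits were tested on simulated data with 200 probe sets changed by known amounts among 6984. In the simulated 24 h comparison 32.8% of 1.5-fold, 92.5% of 2-fold and 100% of 4-fold changes were recovered, with 3.85% false among the calls. The figures at 48 h were 44.8%, 88.1% and 100%, with 8.28% false. For the difference between the times they were 13.4%, 59.7% and 100%, with 6.50% false, and over both times 86.6%, 98.5% and 100%, with 4.04% false. In 50 simulated rounds at 24 h camera found a list of 14 genes, each shifted by 0.8 log2, in 100% of rounds. It called 0.0714% of unchanged lists. Smaller shifts of a list were not simulated. The simulated noise was independent between genes. The estimated correlation within the 20S core list was 0.73, so these rates do not hold for lists of correlated genes.

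The alternatives tried were other pseudocounts, other scalings, other filters on low probe sets, no design covariate, the U74Av2 arrays alone, the replicate number as a block, other variance models, the groups of 1 time alone, each array left out in turn, and, chosen after seeing the data, an average of lactacystin 24 h replicates 2 and 3. Those 2 arrays were the most alike (r = 0.990 across probe sets), and were counted as separate samples. The 2445 probe sets found on U74Av2 alone were fitted separately on its 6 arrays. Figures were drawn with matplotlib 3.10.9.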

Results

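Gene expression was measured in mouse primary cortical neurons after 24 h or 48 h with 1 µM lactacystin, which blocks the proteasome, and in control cultures of the same times. The series addresses the transcriptional course of neuronal death under lactacystin. The groups held 2 control and 3 lactacystin arrays at each time, and 6984 probe sets were tested. The first principal component, with 45.3% of the variance, followed array design, the next (21.5%) followed treatment, and the one after (12.3%) followed time under lactacystin. Log2 changes with their errors and p-values are adjusted for array design unless another setting is named, and mean signals are not adjusted for it.

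At 24 h all 14 genes of the proteasome 20S core rose, as did 8 of 13 NRF2 antioxidant genes and 7 of 18 heat shock genes, and 11 of 12 cholesterol synthesis genes fell. Hspa1a, an inducible cytosolic chaperone, went from a mean signal of 325.2 ± 139 (SD, n = 2) to 5299 ± 3158 (SD, n = 3), a rise of 3.49 ± 0.30 log2 (SE, adjusted p = 4.58e-05). Srxn1, which repairs oxidised peroxiredoxins, rose by 3.66 ± 0.51 (adjusted p = 0.000859). Idi1 and Fdps, enzymes of the mevalonate pathway, changed by -2.52 ± 0.14 and -2.13 ± 0.12 (adjusted p = 4.59e-06 for each). In all 1032 probe sets passed the threshold, 569 higher and 463 lower, of which 147 and 59 changed at least 2-fold.

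All 14 genes of the proteasome 20S core rose at 24 h, with a median of 0.89 log2, and 14 did so when adjusted over the list alone. Psmb3 rose by 1.55 ± 0.15, Psmb1 by 0.89 ± 0.13 and Psma2 by 0.82 ± 0.13. Of 14 measured genes of the 19S regulator, which recognises and unfolds substrates, 12 rose (13 adjusted over the list alone), with a median of 0.82. Psmc3 rose by 1.29 ± 0.11 and Psmd7 by 0.78 ± 0.12, while Psmd2 stood at 0.09 ± 0.27. The medians within U74A and within U74Av2 were 1.04 and 0.89 for the core, and 0.79 and 0.85 for the regulator. Both lists lay above the other genes in camera (adjusted p = 1.55e-13 and 1.90e-11), but with adjusted p = 0.186 and adjusted p = 0.124 with an estimated correlation. Among the immunoproteasome and PA28 genes 1 of 4 rose, the peptide transporter Tap1 (0.86 ± 0.19), also 1 adjusted over the list alone, and the list was not past the threshold.

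Of 18 genes of the cytosolic heat shock response 7 rose and none fell at 24 h (8 rose adjusted over the list alone), among them Hspa1a, Hspa1b (2.19 ± 0.39) and the co-chaperone Bag3 (1.04 ± 0.30). Hspa1a and Hspa1b are near-identical copies, and their probe sets are reported as uncertain between the 2 genes. The list passed camera (adjusted p = 0.000143; adjusted p = 0.186 with an estimated correlation). Among 13 NRF2 antioxidant genes 8 rose and none fell (11 rose adjusted over the list alone), including Gsta4 (2.06 ± 0.30), Nqo1 (1.37 ± 0.33, its other probe set at 0.84 and just not past the threshold) and the regulator Nfe2l2 itself (1.49 ± 0.15). This list had a median of 0.98. Camera gave the list adjusted p = 1.13e-06, and adjusted p = 0.282 with an estimated correlation. The ATF4 and amino acid stress list had 4 of 16 risen (6 adjusted over the list alone), with the stress transcription factor Atf3 at 2.34 ± 0.29 (its other probe set at 0.89, adjusted p = 0.0590) and Atf4 at -0.12 ± 0.15, not past the threshold. This group had camera adjusted p = 0.00668, and adjusted p = 0.418 with an estimated correlation. Of 14 genes of the ER unfolded protein response 1 rose (1 adjusted over the list alone), and the list was not past the threshold.

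Among 11 targets of p53, 6 rose and none fell at 24 h (6 adjusted over the list alone), with Gadd45a at 1.87 ± 0.19, Perp at 1.62 ± 0.19 and the cell cycle inhibitor Cdkn1a at 1.34 ± 0.15. For the list camera gave adjusted p = 0.00048, and adjusted p = 0.135 with an estimated correlation. Of the immediate early genes 5 of 14 rose (6 adjusted over the list alone), including Ier3 (2.51 ± 0.26) and Egr1 (1.01 ± 0.21), and the list passed camera (adjusted p = 0.00524; adjusted p = 0.186 with an estimated correlation). The metal-binding metallothioneins Mt1 (1.45 ± 0.23) and Mt2 (1.06 ± 0.19) rose, and Mt3 did not pass (0.14 ± 0.13), so 2 of 3 rose, also adjusted over the list alone. As a group these had camera adjusted p = 0.0234, and adjusted p = 0.381 with an estimated correlation. Of 24 autophagy and lysosome genes 5 rose (5 adjusted over the list alone), with the protease Ctsd at 1.05 ± 0.17 and Lamp2 at 1.00 ± 0.14. The list had camera adjusted p = 0.0234, and adjusted p = 0.418 with an estimated correlation. In the cytokine list 1 of 7 rose (1 adjusted over the list alone), the macrophage growth factor Csf1 at 1.41 ± 0.14 (camera adjusted p = 0.0496; adjusted p = 0.297 with an estimated correlation), and of 27 cytosolic ribosomal protein genes 3 rose (3 adjusted over the list alone). This group had camera adjusted p = 0.0234, and adjusted p = 0.576 with an estimated correlation. Outside the lists the largest rises included Anxa3 (3.17 ± 0.31), the matrix protein gene Ccn2 (3.03 ± 0.27), the transcription factor gene Fosl1 (3.02 ± 0.24) and the collagen chaperone gene Serpinh1 (2.49 ± 0.19).

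Of 12 measured cholesterol synthesis genes 11 fell and none rose at 24 h (12 fell adjusted over the list alone), with a median of -1.58 log2. Besides Idi1 and Fdps these included Dhcr7 (-1.77 ± 0.23) and Fdft1 (-1.71 ± 0.12), and the fatty acid desaturase gene Scd1, outside the list, changed by -2.45 ± 0.30. The list passed camera (adjusted p = 1.55e-13; adjusted p = 0.124 with an estimated correlation), with medians of -1.56 within U74A and -1.63 within U74Av2. Of 25 genes of the neuronal cytoskeleton and growth 13 fell (16 adjusted over the list alone), including the microtubule regulator Stmn2 (-0.74 ± 0.11) and the growth cone protein gene Gap43 (-0.38 ± 0.09), and the list passed camera (adjusted p = 1.30e-07; adjusted p = 0.124 with an estimated correlation). Of 17 synaptic genes 5 fell (5 adjusted over the list alone), such as Nrgn (-1.38 ± 0.28) and Stx1a (-0.90 ± 0.19). For the list camera gave adjusted p = 0.0169, and adjusted p = 0.408 with an estimated correlation.

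Cell type markers moved at the same time. Of 9 neuron markers 3 fell (4 adjusted over the list alone), with a median of -0.45. Camera gave the list adjusted p = 0.0145, and adjusted p = 0.186 with an estimated correlation. Of 9 astrocyte and radial glia markers 3 fell and 1 rose (the same counts adjusted over the list alone), with a median of -0.47. The water channel gene Aqp4 changed by -1.89 ± 0.18, Apoe by -0.95 ± 0.26 and the intermediate filament gene Gfap by -0.64 ± 0.15, while the gap junction gene Gja1 rose by 1.04 ± 0.16. This group had camera adjusted p = 0.0299, and adjusted p = 0.282 with an estimated correlation. Of the microglia and macrophage markers 1 of 10 rose, Cd68 (1.41 ± 0.27; 1 adjusted over the list alone), and of the fibroblast, mural and meningeal markers 1 of 11, Tagln (1.24 ± 0.27; 3 adjusted over the list alone), and neither list passed. The lists for the ubiquitin system (3 of 11 risen, 2 fallen), apoptosis promoting (1 of 11 risen, Bid at 0.64 ± 0.16) and inhibiting genes (0 of 9), the cell cycle (2 of 27 risen), glycolysis (2 of 13 risen, among them Hk2 at 1.76 ± 0.18), oxidative phosphorylation (2 of 38 risen, 2 fallen), and the oligodendrocyte, endothelial and erythroid markers (0 of 3 each) did not pass camera.

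The call count at 24 h rested on few arrays. It was 308 (205 higher, 103 lower) without control replicate 2, 590 without control replicate 1 and 681 without lactacystin replicate 2, and 558 on the U74Av2 arrays alone. Without control replicate 1 the astrocyte list had camera adjusted p = 0.0802, the metallothioneins 0.118, the ribosomal proteins 0.118, autophagy and lysosome 0.0625 and the cytokines 0.349. Without control replicate 2 the immediate early genes had 0.0582 and the astrocyte list 0.0542. Without lactacystin replicate 1 the metallothioneins had 0.110, the synaptic list 0.135, the ribosomal proteins 0.254, autophagy and lysosome 0.0503 and the cytokines 0.121, and without lactacystin replicate 3 the cytokines had 0.0523 and the astrocyte list 0.0529. The cytokine call also ended without any of the 5 arrays of 48 h (0.0503 to 0.0572). Over all 6984 probe sets, 69.0% had the same sign of change within both array designs.

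**Figure D1:**
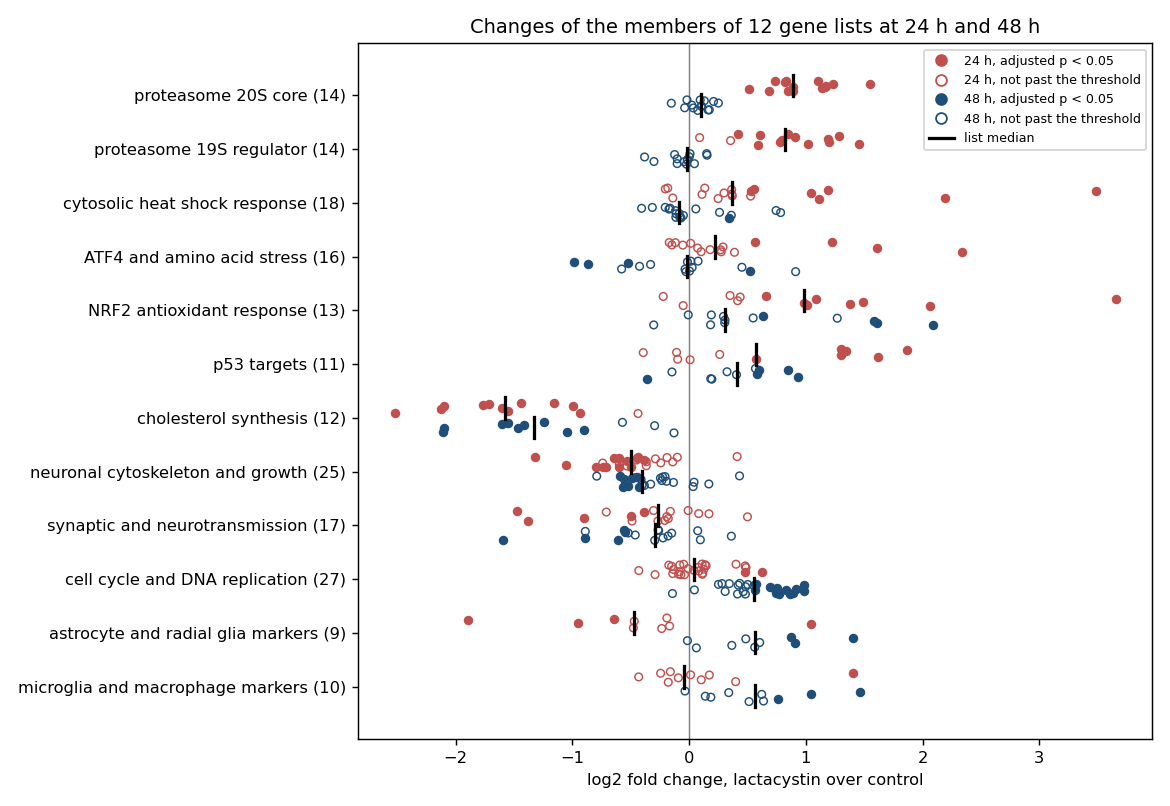
Log2 fold change of lactacystin over control (horizontal axis) for the measured members of 12 gene lists (vertical axis, number of members in parentheses), at 24 h in red and at 48 h in blue; filled points passed an adjusted p of 0.05 in limma, open points did not, and black bars are list medians. The median of the proteasome 20S core is 0.89 at 24 h and 0.10 at 48 h, and that of cholesterol synthesis is -1.58 and -1.33.

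At 48 h all 3 metallothioneins and 13 of 27 cell cycle genes rose, and 9 of 12 cholesterol synthesis genes fell. Lgals1, a secreted galectin, went from a mean signal of 454.5 ± 69.5 (SD, n = 2) to 2988 ± 509 (SD, n = 3), a rise of 2.63 ± 0.24 log2 (adjusted p = 0.000123). Anxa3 rose by 2.89 ± 0.31, the detoxifying hydrolase gene Ephx1 by 2.63 ± 0.25, Ptgr1 by 2.54 ± 0.35 and Ccn2 by 2.51 ± 0.27. Scd1 changed by -2.64 ± 0.30 and the neuropeptide genes Sst and Npy by -1.88 ± 0.27 and -1.37 ± 0.18. In all 721 probe sets passed, 472 higher and 249 lower, with 135 and 30 at least 2-fold changed.

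None of the 14 genes of the proteasome 20S core and none of the 14 of the 19S regulator passed at 48 h, over all probe sets or adjusted over the list alone, with medians of 0.10 and -0.02. In the heat shock list 1 of 18 rose (0 adjusted over the list alone), and Hspa1a stood at 0.74 ± 0.30, not past the threshold. Without lactacystin 24 h replicate 1 Hspa1a passed (adjusted p = 0.0241). All 3 metallothioneins rose (3 adjusted over the list alone), with Mt1 at 2.13 ± 0.23, Mt2 at 1.57 ± 0.19 and Mt3 at 0.98 ± 0.13. For the list camera gave adjusted p = 0.000411, and adjusted p = 0.220 with an estimated correlation. Of 13 NRF2 genes 4 rose (4 rose and 1 fell adjusted over the list alone), including Gsta4 (2.09 ± 0.30), Nqo1 (1.61 ± 0.33) and Nfe2l2 (1.58 ± 0.15). As a group these had camera adjusted p = 0.00357, and adjusted p = 0.545 with an estimated correlation. Of 11 p53 targets 4 rose and 1 fell (7 and 1 adjusted over the list alone), with Perp at 0.93 ± 0.19 and Gadd45a at 0.85 ± 0.19. As a group these had camera adjusted p = 0.0135, and adjusted p = 0.220 with an estimated correlation. In the cytokine list 2 of 7 rose (2 adjusted over the list alone), Csf1 (1.12 ± 0.14) and the adhesion molecule gene Vcam1 (1.09 ± 0.15, its other probe set at 0.31, adjusted p = 0.312). The list had camera adjusted p = 0.0450, and adjusted p = 0.308 with an estimated correlation.

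Of 27 cell cycle and DNA replication genes 13 rose and none fell at 48 h (19 rose adjusted over the list alone), with a median of 0.56. These included Top2a (0.99 ± 0.19), the replication helicase genes Mcm3 (0.98 ± 0.19) and Mcm4 (0.91 ± 0.12) and the proliferation marker Mki67 (0.89 ± 0.19). The list passed camera (adjusted p = 3.84e-09; adjusted p = 0.199 with an estimated correlation), with medians of 0.81 within U74A and 0.41 within U74Av2. In the controls the median of the list from 24 h to 48 h was -0.26, with no gene past the threshold (camera adjusted p = 1.53e-05; adjusted p = 0.904 with an estimated correlation).

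Of the cholesterol synthesis genes 9 of 12 fell at 48 h (10 adjusted over the list alone), with a median of -1.33, Idi1 and Fdps both at -2.10, and SE of 0.14 and 0.12. The list had camera adjusted p = 2.26e-13, and adjusted p = 0.148 with an estimated correlation. Of 25 neuronal cytoskeleton and growth genes 7 fell (13 adjusted over the list alone), with Stmn2 at -0.57 ± 0.11 and Gap43 at -0.56 ± 0.09. Camera gave the list adjusted p = 5.29e-07, and adjusted p = 0.148 with an estimated correlation. Of 17 synaptic genes 5 fell (7 adjusted over the list alone), led by Nrgn at -1.60 ± 0.28. This group had camera adjusted p = 0.000154, and adjusted p = 0.220 with an estimated correlation. In the ATF4 list 1 rose and 3 fell of 16 (3 and 5 adjusted over the list alone), with Atf4 at -0.99 ± 0.15 and the folate enzyme gene Mthfd2 at -0.86 ± 0.17, and the list was not past the threshold. It passed camera without control 48 h replicate 2 (adjusted p = 0.0367).

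Of the cell type markers, 2 of 9 for neurons fell at 48 h (4 adjusted over the list alone), with a median of -0.40. For the list camera gave adjusted p = 0.00139, and adjusted p = 0.148 with an estimated correlation. Of 9 astrocyte and radial glia markers 3 rose and none fell (4 rose adjusted over the list alone), Gfap at 1.40 ± 0.15, Gja1 at 0.90 ± 0.16 and Ntsr2 at 0.87 ± 0.17, with a median of 0.56. As a group these had camera adjusted p = 0.00284, and adjusted p = 0.199 with an estimated correlation. The other probe set of Gfap stood at 0.77 and did not pass (adjusted p = 0.0951). Of 10 microglia and macrophage markers 3 rose (5 adjusted over the list alone), Cd68 at 1.47 ± 0.27, Tyrobp at 1.04 ± 0.27 and Ctss at 0.76 ± 0.17. The list had camera adjusted p = 0.00504, and adjusted p = 0.363 with an estimated correlation. Of 11 fibroblast, mural and meningeal markers 3 rose (4 adjusted over the list alone), among them the contractile protein genes Tagln (2.12 ± 0.27) and Acta2 (2.10 ± 0.33), with Col1a1 at 0.40 ± 0.18, not past the threshold. Camera gave the list adjusted p = 0.0294, and adjusted p = 0.545 with an estimated correlation. The autophagy and lysosome list had 5 risen and 1 fallen of 24 (10 and 2 adjusted over the list alone), with Lamp2 at 1.15 ± 0.14, and did not pass. Nor did the immunoproteasome (0 of 4), ubiquitin (0 of 11), ER (1 of 14 fallen, Xbp1 at -0.66 ± 0.18), immediate early (1 of 14 risen, Egr1 at 0.74 ± 0.21), ribosomal (2 of 27 risen), apoptosis promoting (0 of 11) and inhibiting (0 of 9), glycolysis (0 of 13), oxidative phosphorylation (0 of 38), oligodendrocyte, endothelial and erythroid lists (0 of 3 each). The ubiquitin list passed camera without control 24 h replicate 1 or 2 (adjusted p = 0.0385 for each), and the endothelial list without control 48 h replicate 2 (adjusted p = 0.0308).

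Without control replicate 1 of 48 h the count was 234, and without control replicate 2 it was 213 (174 higher, 39 lower), with 439 from the arrays of 48 h alone and 385 on the U74Av2 arrays. Without control replicate 1 the adjusted p was 0.0930 for Nqo1, 0.0796 for Perp, 0.0886 for Top2a, 0.0956 for Mcm3, 0.136 for Mki67, 0.0663 for Nrgn, 0.106 for Mthfd2, 0.254 for Xbp1, 0.295 for Egr1, 0.0616 for Tyrobp and 0.106 for Ctss. Without control replicate 2 it was 0.0901 for Nqo1, 0.0952 for Perp, 0.205 for Gadd45a, 0.154 for Stmn2, 0.0890 for Gap43, 0.109 for Gja1, 0.113 for Ntsr2, 0.115 for Cd68, 0.313 for Tyrobp, 0.115 for Ctss, 0.0952 for Xbp1 and 0.0933 for Egr1. Tyrobp also lost its call without lactacystin 48 h replicate 1 (0.0524), 2 (0.0749) or 3 (0.0728), Xbp1 without 48 h replicate 1 (0.0949) or 2 (0.0603) or 24 h replicate 2 (0.0532) or 3 (0.0527) of lactacystin, and Ctss without 48 h replicate 2 (0.0546). Egr1 lost it without any lactacystin array, at 0.0514 to 0.111. Of the lists, p53 targets (0.0682) and microglia markers (0.0634) were not past the threshold without control replicate 2. The fibroblast list was at 0.197 without control replicate 1, and at 0.169 and 0.0945 without lactacystin 48 h replicates 1 and 3. The cytokine list was at 0.0591 and 0.0765 without control 48 h replicates 1 and 2, at 0.0671 and 0.128 without lactacystin 48 h replicates 1 and 3, and at 0.0547 and 0.0502 without lactacystin 24 h replicates 1 and 2.

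The changes at the 2 times were related. Across genes, which are not independent replicates, the log2 changes at 24 h and 48 h had a correlation of 0.52, against 0.014 from the shared design alone, and a covariance of 0.0872 against 0.000499. Of the probe sets higher at 24 h and those higher at 48 h, 184 were in both sets, with 38.5 for independent lists, and 130 were lower at both times, with 16.5 for independent lists. Another 12 were called in opposite directions.

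The effect at 48 h minus the effect at 24 h asks which responses differed between the times. Of the named genes past the threshold Hspa1a had the largest negative difference, -2.74 ± 0.42 log2 (adjusted p = 0.0113), followed by Ier3 (-2.07 ± 0.37), Zbtb17 (-1.98 ± 0.37), Fosl1 (-1.95 ± 0.33) and the hexokinase gene Hk2 (-1.59 ± 0.25). Aqp4 (2.38 ± 0.25, adjusted p = 0.00185), Glycam1 (2.09 ± 0.30), Gfap (2.04 ± 0.21), Ednrb (1.99 ± 0.43) and Pla2g7 (1.82 ± 0.29) had the largest positive differences past the threshold. In all 90 probe sets passed, 31 positive and 59 negative. Of the 20S core 7 of 14 genes and of the 19S regulator 9 of 14 had a negative difference past the threshold (14 and 12 adjusted over the list alone), with medians of -0.76 and -0.86 (camera adjusted p = 1.06e-15 for each; adjusted p = 0.256 and adjusted p = 0.0577 with an estimated correlation). Of the heat shock genes 4 of 18 (7 adjusted over the list alone) and of the ATF4 list 2 of 16 (9 adjusted over the list alone) had a negative difference (camera adjusted p = 1.08e-06 and 1.20e-06; adjusted p = 0.204 and adjusted p = 0.256 with an estimated correlation). The astrocyte list had 2 of 9 positive (5 adjusted over the list alone). Camera gave the list adjusted p = 2.15e-05, and adjusted p = 0.157 with an estimated correlation. In the cell cycle list 1 of 27, Mcm4 (0.78 ± 0.16), was positive (12 adjusted over the list alone). This group had camera adjusted p = 1.08e-06, and adjusted p = 0.256 with an estimated correlation.

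Other lists past camera had few single genes past the threshold. The ubiquitin system had 2 of 11 negative (4 adjusted over the list alone). Its camera adjusted p was 0.0154, with adjusted p = 0.460 with an estimated correlation, and 0.103 without control 24 h replicate 2. The NRF2 list had 1 of 13 negative, the superoxide dismutase gene Sod1 (1 positive and 3 negative adjusted over the list alone). Camera gave 0.0162, with adjusted p = 0.605 with an estimated correlation, and 0.0708, 0.136 and 0.242 without control 24 h replicate 2, lactacystin 24 h replicate 1 and lactacystin 48 h replicate 3. No p53 target passed (4 negative adjusted over the list alone). The p53 list had 0.0154 in camera, with adjusted p = 0.256 with an estimated correlation, and 0.0571 without control 24 h replicate 1. Of the immediate early genes 1 of 14, Ier3, was negative (1 adjusted over the list alone). That list had 0.0435 in camera, with adjusted p = 0.347 with an estimated correlation. It had 0.367, 0.271, 0.0563 and 0.0554 without control 24 h replicate 2, control 48 h replicate 2, lactacystin 24 h replicate 3 and lactacystin 48 h replicate 1. No cholesterol synthesis gene passed (0 adjusted over the list alone). The cholesterol list had 0.0487 in camera, with adjusted p = 0.605 with an estimated correlation. It had 0.440, 0.248, 0.153 and 0.242 without control 24 h replicate 2, control 48 h replicate 2, lactacystin 24 h replicate 1 and lactacystin 48 h replicate 3. No microglia marker passed either (0 adjusted over the list alone). The microglia list had 0.0180 in camera, with adjusted p = 0.500 with an estimated correlation, and 0.103, 0.133 and 0.0706 without control 24 h replicate 2, control 48 h replicate 2 and lactacystin 48 h replicate 2.

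The count for this difference was 5 without control 48 h replicate 1, 31 (14 positive, 17 negative) without control 48 h replicate 2, 18 (3 positive, 15 negative) and 16 without control 24 h replicates 1 and 2, 187 (88 positive, 99 negative) without lactacystin 24 h replicate 1, and 39 without lactacystin 24 h replicate 2 or 3. It was 12 on the U74Av2 arrays alone. Gfap and Aqp4 kept adjusted p under the threshold without any 1 array. For Hspa1a it was 0.0505, 0.106 and 0.0711 without control 24 h replicate 1, control 24 h replicate 2 and control 48 h replicate 1, for Pla2g7 0.0670, 0.0990 and 0.0992, and for Glycam1 0.0576 and 0.0631 without replicate 1 of the 24 h and of the 48 h controls. Hk2 was at 0.0600 without control 24 h replicate 1, and at 0.0706 and 0.0565 without control 48 h replicates 1 and 2. Ier3 and Fosl1 lost their calls without any 1 control array or without lactacystin 24 h replicate 2 or 3 (0.0590 to 0.150 and 0.0571 to 0.0974). Zbtb17 also lost its call without those 6 arrays and without lactacystin 48 h replicates 1 and 3 (0.0528 to 0.173), and Ednrb kept its call only without control 48 h replicate 2 or lactacystin 48 h replicate 2 (otherwise 0.0501 to 0.181).

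In control cultures no probe set differed between 48 h and 24 h by limma (0 past the threshold), while 390 had an unadjusted p under 0.05, with 349.2 for no effect. The smallest adjusted p was 0.386. The named genes with the smallest p, none past the threshold, were Slc7a3 (-0.74 ± 0.14), Atf5 (-1.03 ± 0.20), Cdc16 (0.79 ± 0.16), Gadd45g (-0.75 ± 0.15) and Cck (0.71 ± 0.15), and the count was 1 and 2 without control 24 h replicates 1 and 2. Atf5 passed without control 24 h replicate 1 (adjusted p = 0.0308). The cell cycle list (median -0.26, camera adjusted p = 1.53e-05) and the ATF4 list (median -0.22, camera adjusted p = 6.39e-05) were lower at 48 h, with no gene past the threshold in either over all probe sets, and 0 and 1 fallen adjusted over the list alone. Both had adjusted p = 0.904 with an estimated correlation.

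Under lactacystin 803 probe sets differed between 48 h and 24 h, 432 higher and 371 lower at 48 h. This balance turned with quantile normalization (387 higher, 419 lower), and without lactacystin 24 h replicate 2 (172, 173) or 3 (155, 168) or 48 h replicate 2 (283, 286) or 3 (258, 264). Aqp4 rose by 2.33 ± 0.16 (adjusted p = 1.29e-05), Glycam1 by 2.06 ± 0.19, Gfap by 2.01 ± 0.13, Apoe by 1.95 ± 0.23 and Pla2g7 by 1.91 ± 0.18, and Hspa1a fell by 2.59 ± 0.27 on the log2 scale, with Hspa1b at -2.31 ± 0.35, Srxn1 at -2.18 ± 0.45 and the amino acid transporter gene Slc7a3 at -2.09 ± 0.12. All 14 genes of the 20S core and 12 of 14 of the 19S regulator fell (14 and 13 adjusted over the list alone; camera adjusted p = 1.10e-15 and 1.52e-14; adjusted p = 0.226 and adjusted p = 0.0718 with an estimated correlation), as did 12 of 16 ATF4 and amino acid stress genes (13 adjusted over the list alone). For the list camera gave adjusted p = 6.44e-13, and adjusted p = 0.160 with an estimated correlation. Of 9 astrocyte markers 5 rose (6 adjusted over the list alone). As a group these had camera adjusted p = 3.67e-06, and adjusted p = 0.113 with an estimated correlation. The count was 345 and 323 without lactacystin 24 h replicates 2 and 3, and 516 and 522 without lactacystin 48 h replicates 1 and 3.

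Over both times together, 6 lactacystin arrays against 4 controls gave 1187 probe sets past the threshold, 662 higher and 525 lower, and Anxa3, Ccn2, Ptgr1, Ephx1 and Lgals3 had the largest rises, Scd1, Idi1, Fdps, Nsdhl and Dhcr7 the largest falls. Of the lists 13 of 29 passed camera, none with an estimated correlation (smallest adjusted p = 0.0983). Cholesterol synthesis genes (11 of 12 fallen, median -1.44) and neuronal cytoskeleton and growth genes (16 of 25 fallen, median -0.44) were lower, with 11 and 19 fallen adjusted over the list alone. The NRF2 genes (9 of 13 risen, median 0.60) and the p53 targets (7 of 11 risen, median 0.42) were higher, with 10 and 7 risen adjusted over the list alone. The count was 763 without control 24 h replicate 2.

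**Figure D2:**
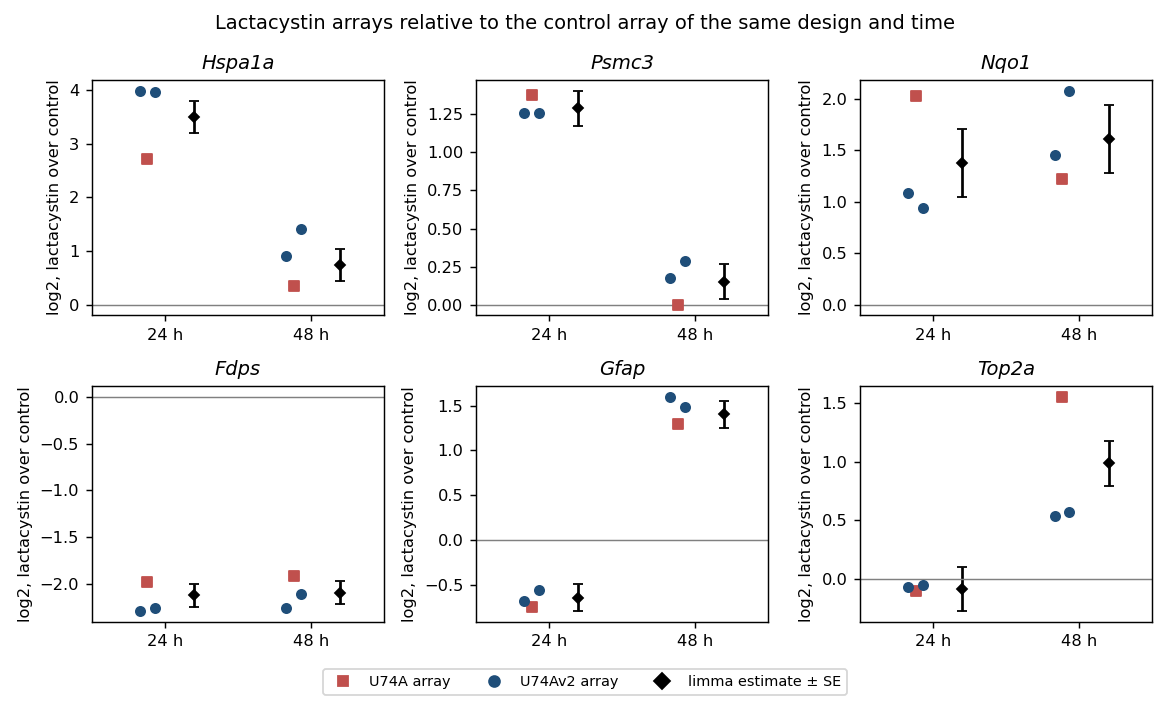
Log2 difference of each lactacystin array from the control array of the same design and time (vertical axis) for 6 genes at 24 h and 48 h (horizontal axis); squares are U74A arrays, circles U74Av2 arrays, and black diamonds the limma estimate with its standard error. Gfap lies below 0 at 24 h and above 0 at 48 h on every array, with estimates of -0.64 and 1.40, and Fdps lies below 0 on every array at both times.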

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

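The comparison of the lactacystin effects at 48 h and 24 h, its list tests, the tests of signal-dependent bias and the splits of all 10 arrays were planned, while the other tests of explanations, the splits within array design and time included, were chosen after the result was seen. Among these, the test of whether the astrocyte markers changed alike at 48 h was added after a first test of the neuron share had already returned its value.

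The lactacystin effect differed between 48 h and 24 h, by a test of the difference itself, for 90 probe sets. Among named genes the difference was -2.74 for Hspa1a, -2.07 for Ier3, -1.98 for Zbtb17, -1.95 for Fosl1, -1.59 for Hk2, -1.34 for Slc7a3, -1.30 for Psmb3, -1.28 for Ufd1, -1.13 for Psmc3, -1.08 for Psmd7 and -0.98 for Cdc16 on the log2 scale. It was 0.78 for Mcm4, 1.82 for Pla2g7, 1.99 for Ednrb, 2.04 for Gfap, 2.09 for Glycam1 and 2.38 for Aqp4. Among lists past camera the median difference was -0.76 for the 20S core, -0.86 for the 19S regulator, -0.35 for the ubiquitin system, -0.38 for heat shock, -0.54 for ATF4, -0.25 for NRF2, -0.39 for p53 targets and -0.26 for immediate early genes. It was 0.50 for the cell cycle, 0.25 for cholesterol synthesis, 1.04 for astrocyte markers and 0.51 for microglia markers. None of these lists passed with an estimated correlation (smallest adjusted p = 0.0577). For the cell cycle list the median from 24 h to 48 h was -0.26 in the controls and 0.27 under lactacystin. Part of its difference therefore lay in the controls.

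Probe sets found on U74Av2 alone were tested with 1 control array at each time, so the spread between controls was not measured and only that of the lactacystin arrays entered. Of 1430 tested on 6 arrays with 2 residual degrees of freedom, 101 passed at 24 h and 63 at 48 h. Hspb8 (2.89 at 24 h, 1.79 at 48 h), Hmox1 (2.59 and 1.78), Mvd (-3.16 and -2.08) and Msmo1 (-1.63 and -1.80) passed at both times.

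At 24 h 14 of 14 genes of the proteasome 20S core and 12 of 14 of the 19S regulator rose, with adjusted p = 0.186 and 0.124 for the lists with an estimated correlation, and none passed at 48 h. The tables argue against a change in the controls (control median 0.0322 from 24 h to 48 h, lactacystin median -0.83), against 1 array design carrying it (median difference -1.01 within U74A, -0.79 within U74Av2) and against signal-dependent bias (0 of 10000 random lists of like signal had a median as low as -0.80). A transient response to lactacystin is consistent with these values as a hypothesis.

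Of 9 astrocyte markers 3 fell and 1 rose at 24 h, and 3 rose at 48 h, with adjusted p = 0.282 and 0.199 for the list with an estimated correlation; the 24 h camera call ended without control replicate 1 (0.0802) or 2 (0.0542) or lactacystin replicate 3 (0.0529). At 24 h a lower share of neurons would raise them, and their median was -0.47 (fry adjusted p = 0.0120); the controls changed by -0.0017 from 24 h to 48 h, against 0.86 under lactacystin. At 48 h the first test left a lower neuron share possible: the 5 non-neuronal lists showed no difference past the threshold (permutation p = 0.402), all with medians above 0, the lowest 0.12, which does not show that they moved alike. A second test, added after that value was known, found unequal changes among the astrocyte markers (a fraction of 8.00e-05 of simulations from their standard errors varied as much). It is neither an exact nor a permutation test, and takes errors as independent between genes. It also assumes that a lower share would change all markers alike on the log2 scale. The pseudocount understates changes of low genes, and the probe sets of Gfap differed at 48 h (1.40 and 0.77). Unequal changes can therefore arise under a lower share too, and the test cannot decide this. From 24 h to 48 h the neuron marker median moved by 0.053 in the controls and by 0.11 under lactacystin. Neuron markers thus showed no further fall while the astrocyte markers rose. A neuron share equally low at both times would not alone turn the astrocyte markers from lower to higher. A lower share may account for their 48 h level over control in part or whole, and a change in astrocytes themselves stays open.

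Of 12 cholesterol synthesis genes 11 fell at 24 h and 9 at 48 h, with adjusted p = 0.124 and 0.148 for the list with an estimated correlation. The list lay below the neuron markers at both times (one-sided permutation of genes, larger p = 0.00424, smaller p = 0.00163). This permutation takes genes as independent, so its p measures the spread between genes and not between cultures. With that limit, a lower neuron share alone is unlikely. Against signal-dependent bias, 0 of 10000 random lists of like signal had as low a median at either time. Within designs and times the medians ran from -1.24 to -1.63, against 1 design carrying it. Lower transcription of the pathway under lactacystin is a candidate explanation that was not itself tested. The other explanations were tested on the same data that gave the pattern.

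For the comparison over both times, 1 of 100 splits of the 10 arrays into 6 and 4 (of 210 possible), the real one, gave as many as 1187 probe sets, and the highest other split gave 105. Those splits mix array designs and times. Of all 36 splits that keep 1 control in each array design and time, 1, the real one, gave as many. The highest other gave 1 probe set. The share of splits with as many was under 0.05 in both sets. Each other split put 1 or more lactacystin arrays among the controls, so its count does not measure a level without treatment effect. With the real split counted, 1 of 36 is the smallest share that set can give. Such splits take arrays as independent, and the labels do not say whether replicates were separate cultures. A difference of culture or handling between the agents is therefore not excluded.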

How the results depend on the processing

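The average of lactacystin 24 h replicates 2 and 3 was chosen after seeing the data; all other alternatives were planned. No call reversed among the genes and lists followed across these settings. The balance of calls over time under lactacystin turned, from 432 higher and 371 lower to 387 and 419 with quantile normalization, 289 and 295 with no filter, 54 and 79 without the design covariate, 162 and 171 with averaged replicates, and 23 and 34 with the replicate block in place of design. It was 334 and 334 on U74Av2 alone. It also turned without lactacystin 24 h replicate 2 (172 and 173) or 3 (155 and 168) and without lactacystin 48 h replicate 2 (283 and 286) or 3 (258 and 264). The number of arrays limits these tests, and a lone control left after an omission is assumed to vary like the other groups. Causes were not tested, except that fewer arrays were fitted with U74Av2 alone, averaged arrays, 1 time or an array left out. The main counts were 1032 at 24 h, 721 at 48 h, 90 for the difference, 803 over time under lactacystin, 1187 over both times and 0 over time in control.

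Without the design covariate the counts were 250, 113, 2, 133 and 486 in that order. On U74Av2 arrays alone, with 1 control array at each time, they were 558, 385 and 12 for the first 3 comparisons and 524 over both times. With the replicate averages they were 680 at 24 h, 40 for the difference and 333 over time under lactacystin. The difference gave 48 with no filter and 37 without the variance trend, and 48 h gave 439 from its own arrays alone. The ratio of higher to lower calls moved by over 1.5 times without the design covariate (175 and 75 at 24 h, 1 and 1 for the difference) and with the block in place of design (130 and 41 at 24 h, 61 and 20 at 48 h). It did so without the variance trend (433 and 150 at 48 h, 18 and 19 for the difference) and with no filter (12 and 36 for the difference). With 1 array left out the ranges were 308 to 1100 at 24 h, 213 to 827 at 48 h, 5 to 187 for the difference, 323 to 828 over time under lactacystin, 763 to 1145 over both times and 0 to 2 in control.

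The labels share only a replicate number. Deviations of same-numbered arrays from their group means correlated at 0.66 and 0.51 at 24 h, where such arrays also share a design, and control replicate 2 correlated at 0.55 with lactacystin replicate 3, of the same design and another number. At 48 h same-numbered arrays correlated at -0.61 for replicate 1, whose arrays differ in design, and at 0.44 for replicate 2, whose arrays share one. The signs followed array design, so they cannot decide whether a number marks a pair. With design removed the values were -0.28, -0.20, 0.085 and -0.083. The 2 arrays of a control group then mirror each other, so these values cannot decide it either. With the replicate block in place of array design the counts were 171, 81, 0, 57 and 368 in the same order, and with the block beside design 742 over both times; the block beside design moved no other count of calls by over 1.5 times.

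Lists past camera numbered 16 at 24 h, 12 at 48 h and 12 for the difference. With an estimated correlation each was 0. Fry gave 14 at 24 h, 10 at 48 h and 4 for the difference, and U74Av2 alone gave 10 at 24 h. With 1 array left out they ran from 11 to 16, 10 to 13 and 8 to 14. Single genes were followed only in the comparison that named them, and list members at 48 h, with 184 values for each array left out. Calls of list members at 24 h were not followed across the settings unless among the largest changes there. Of the values followed, 1704 stayed on their side of the threshold with 1 array left out, 119 lost the call and 17 gained one. Under other alternatives these were 2323, 177 and 10. Values never past the threshold count among those that stayed. For lists these were 808, 46 and 16, and 1276, 94 and 16.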

Other observations

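The comparisons behind the single-gene calls were planned, while the random-list tests and the choice of both gene families came after the result was seen.

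Annexins and galectins bind membranes and sugars. Of 9 measured genes 8 rose at 24 h (median 1.16) and 7 at 48 h (median 1.45), with Anxa2 at 2.01 and 1.54, Anxa3 at 3.17 and 2.89, and Lgals1 at 1.87 and 2.63. The hypothesis that these genes rose together at both times was set against 10000 random lists of like signal, and the median lay at or above 100% of them at each time. The family was picked because its members were among the largest rises, so this describes the pattern and is no independent evidence. Marker lists of cell types had medians at 48 h of 0.57 for microglia and macrophages, 0.36 for fibroblast, mural and meningeal cells and -0.40 for neurons. At 24 h, when 8 of the 9 family genes had risen, these medians were -0.040, -0.11 and -0.45 in the same order. None of these lists passed with an estimated correlation, and a change in cell shares was not tested for this family.

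Aminoacyl-tRNA synthetase genes, which charge transfer RNAs with amino acids, were compared between 48 h and 24 h under lactacystin. Of 18 genes 14 fell, with a median of -0.67 against -0.17 in control, among them Nars (-1.04) and Rars (-0.97). The hypothesis that these genes fell together had 0% of 10000 random lists of like signal with as low a median. The family was picked because its members fell, so this is no independent evidence. For the difference between the lactacystin effects at 48 h and 24 h the median was -0.54. Of the 18 genes 2 were positive and not past the threshold, and the 2 past it, Rars and Mars1, were negative.

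On U74Av2 alone, Aldoc, an aldolase gene also on the astrocyte list, changed by -1.73 at 24 h and 0.51 at 48 h (not past the threshold), and was the 1 probe set past the threshold there for the difference between the times (2.24). Sparcl1, also an astrocyte-list gene measured on U74Av2 alone, changed by -1.22 at 24 h and -0.34 at 48 h (the latter not past the threshold). With 1 control array at each time the spread between controls was not measured.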
